A study of Mus musculus with 10 samples.

How the data were processed

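RNA sequencing libraries (TruSeq) were made from 1 µg of total RNA of prefrontal cortex, hippocampus and hypothalamus of CF1 mice of postnatal day 56, and 10 libraries were analysed. Per the submitters' processing notes, reads were called with CASAVA, examined with FastQC 0.10.1 and aligned to mm10 with STAR 2.5.0a. The authors deposited raw counts per Ensembl gene, 1 column per library, with no normalization. The counting tool, its strand setting, its treatment of reads that fit several genes and the annotation release are not given in the sources used here. Whether the libraries are separate animals or pools is not given either. Counts of overlapping or antisense genes and of genes with near-identical copies are therefore uncertain.

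Of 47729 genes in the table, 47310 were matched by gene ID to GENCODE M21 (GRCm38), which gave names and coordinates, and 419 were not matched. The female NP hippocampus library had 503 counts for Park7 on chromosome 4 (mean of the other 9 libraries 1282.4), and 0 for the 149 genes that start after it on that chromosome and for the 18943 genes on chromosomes 5 to 9, M, X and Y, which come later in the text order of names. Of 4481 genes on or after this break with a mean of at least 50 counts elsewhere, 4480 had 0 counts in this library, against 4 of 8581 before it. The 19598 genes not placed wholly before Park7 were therefore treated as not measured in this library, and 28131 as measured in all. The 19598 include Park7 itself and the 419 unmatched genes, which had a few counts in this library. The reason for the break is not known.

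Total counts ranged from 7871010 to 16265481 per library, and genes with at least 1 count from 22904 to 25595, with 15288 in the incomplete library. At these depths a gene with 0 counts lies below 3 counts, which is 0.18 to 0.29 CPM in the complete libraries. The incomplete library gave 0.38 CPM over its own total, which lacks the genes not counted there. These limits cover counting error only.

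Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10) and libraries scaled by TMM, in R 4.3.3. Differences were tested with edgeR's quasi-likelihood F test (the current method of glmQLFit), adjusted by Benjamini-Hochberg at 0.05. Diet was tested over 5 strata of region and sex (4 residual degrees of freedom) and within prefrontal cortex and hippocampus from a fit with 1 diet coefficient per region (2 residual degrees of freedom). The difference between regions came from that fit, and the difference between sexes from the 8 libraries of prefrontal cortex and hippocampus (2 residual degrees of freedom). Regions were compared with sex and diet as additive terms (5 residual degrees of freedom), and sexes within strata of region and diet (3 residual degrees of freedom). Genes not measured in 1 library were fitted without it where at least 2 residual degrees of freedom remained, which excluded them from the diet tests within regions, between regions and between sexes. The p-values of both gene sets were adjusted together. Per design each region, sex and diet has 1 library, so single pairs are given as log2 ratios of CPM (prior count 2) with exact 95% Poisson intervals of counts and without p-values. Agreement between pairs was measured with Pearson correlations and an exact sign-flip permutation.

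The 44 gene lists were written before the data were examined, as were the tests, the main settings and the rule for naming genes. Lists with at least 5 tested members were tested with cameraPR of limma 3.58.1 on signed z values with a preset correlation of 0.01. The plan named camera on voom values, which cannot take genes missing from 1 library, so cameraPR was used instead. Companion tests were camera with an estimated correlation and fry. Fry and the estimate of the correlation left out the incomplete library where at least 2 residual degrees of freedom remained. They used 8 libraries for diet over all regions (without the female hippocampus pair), 9 for the region comparisons and 6 for sex. Members are counted over all genes and with p adjusted over the list alone. In single pairs a list's median was ranked among 10000 random lists matched on expression.

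Genes were named by rule. For diet these were the 10 smallest p-values in each direction among genes past the threshold with 1 sign in every pair, and for the tests between regions or sexes of the diet difference the 5 smallest in each direction. For regions they were the 10 largest differences in each direction with mean CPM of at least 10 and separate libraries, and for sex the 10 smallest p-values in each direction. In single pairs they were the 3 largest ratios in each direction (5 in hypothalamus) with mean CPM of at least 10 and separate intervals. Up to 4 members of a list that passed its test, or that passed adjusted over the list alone, were added. A few genes that the rule names are not reported.

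The pipeline was tested on simulated data with the same designs and with changes of 1 and 0.5 on the log2 scale placed in known genes. The tests recovered 86.9% and 76.3% of these genes for diet over all regions (17244 genes; 15 false of 186 calls), 75% and 43% in prefrontal cortex (11244 genes; 14 of 139), and 83.3% and 53% in hippocampus (11231 genes; 17 of 162). For the diet difference between regions they recovered 71.7% and 28% (11231 genes; 12 of 112) and between sexes 64.8% and 16.7% (10751 genes; 10 of 87). For hippocampus against prefrontal cortex they recovered 80.6% and 57.1% (17254 genes; 14 of 159), for hypothalamus 86% and 64.6% (17284 genes; 14 of 174), and for sex 88.7% and 64.2% (16640 genes; 13 of 170). The share of false calls, 7.6% to 11.5%, exceeded the nominal 5%. Of 40 unchanged lists 0 were called in each comparison. Simulated genes varied independently and these lists held random genes, so the result does not cover real lists whose members move together.

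Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, edgeR's earlier method with robust fitting, other designs, other list tests, other prior counts, and leaving out each pair or library in turn. Added after seeing the data were the zeros of the incomplete library kept as deposited, its missing genes added with 1 residual degree of freedom, and counts summed over the regions of each sex and diet. Copies of genes were searched with blastn 2.17.0 in the coding transcripts of the annotation. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.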

Results

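Gene expression was measured by RNA sequencing in the brains of CF1 mice, an outbred stock, at postnatal day 56. The parents had been given a normal-protein (NP) or a low-protein (LP) diet at mating, and each dam remained on that diet while pregnant and nursing. After weaning at postnatal day 21 all offspring received the NP diet for 5 weeks. Prefrontal cortex and hippocampus were profiled in both sexes and hypothalamus in males, with 1 library for each combination of region, sex and diet. The 10 libraries formed 5 LP and NP pairs. Total counts were 12380410 and 13588314 in the male prefrontal cortex (NP, then LP), 10898317 and 10256882 in the female prefrontal cortex. They were 12348735 and 12979367 in the male hippocampus, 7871010 and 11443299 in the female hippocampus, and 16265481 and 14688965 in the hypothalamus. A count of 0 therefore allowed up to 0.18 to 0.29 CPM, counting error only, outside the female NP hippocampus library. That library gave 0.38 CPM over its own total, which lacks the genes described next. The female NP hippocampus library held no counts beyond Park7 on chromosome 4 (GRCm38, 150897133 to 150914437) nor on chromosomes 5 to 9, X, Y and M. Its values for the 19598 genes not placed wholly before Park7, unmatched ones included, were treated as not measured. The other libraries had 33.8% of their counts on these genes. The labels do not say whether libraries came from separate animals or pools, so p-values describe the spread between these libraries. If regions were taken from the same animals, p-values over regions are too small.

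**Figure D1:**
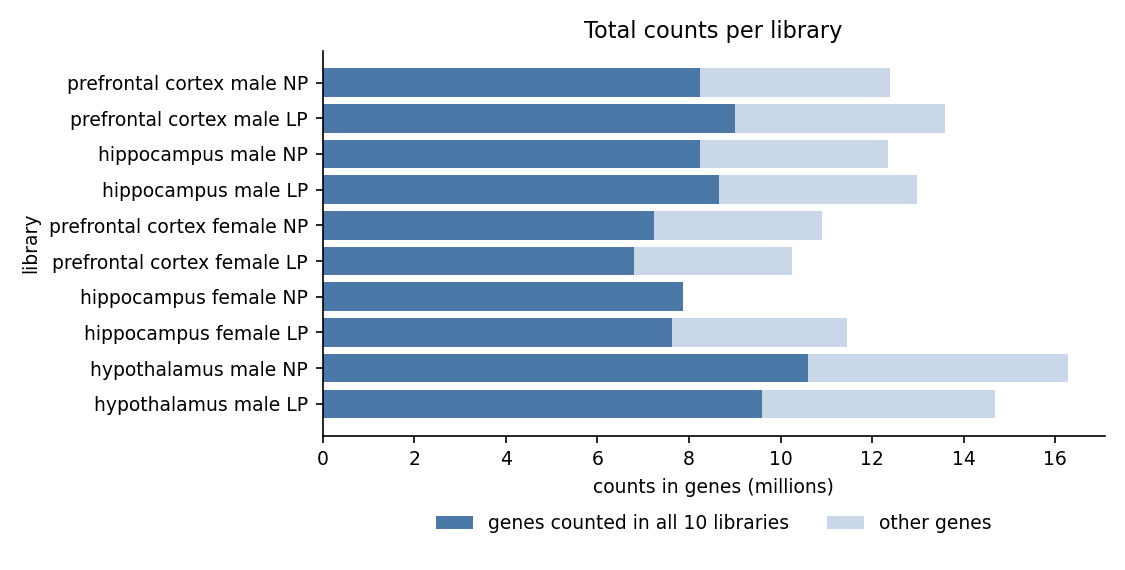
Total counts of each library, divided into genes counted in all 10 libraries (dark) and the other genes (light). The female NP hippocampus library has almost no light part, while its count in the shared genes lies within the range of the others.

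To examine how the perinatal diet altered the adult brain, LP was compared with NP over the 5 pairs (17547 genes). Immediate early genes, which neurons transcribe soon after activity, rose in LP: 16 of 24 members were higher and 8 did not pass, 19 were higher when adjusted over the list alone, and all 24 fold changes were positive (median log2 0.55). Nr4a2, a nuclear receptor gene (ENSMUSG00000026826; GRCm38 chromosome 2, 57106830 to 57124003), rose 1.99-fold (log2 0.99 ± 0.09 SE, 5 pairs, adjusted p = 0.000191), and Homer1, whose short form is induced by synaptic activity, rose 1.54-fold (log2 0.62 ± 0.05, adjusted p = 6.68e-05). Fosl2, an AP-1 subunit gene, rose 1.85-fold over the 4 pairs in which it was counted (0.88 ± 0.07). Heat shock and chaperone genes moved the same way, with 12 of 22 higher, 10 not past the threshold and 18 higher when adjusted over the list alone. Dnajb1, a co-chaperone gene (ENSMUSG00000005483; chromosome 8, 83608193 to 83612653), rose 1.97-fold (0.98 ± 0.07, 4 pairs, adjusted p = 2.95e-05). The small heat shock gene Hspb1 rose 2.57-fold (1.36 ± 0.15) and Hspa5, the endoplasmic reticulum chaperone BiP, rose 1.37-fold (0.45 ± 0.05). Blood transcripts fell: of 8 members 4 globin genes were lower and 4 did not pass (6 lower and 1 higher adjusted over the list alone), with Hba-a2 at -0.61 ± 0.05 (adjusted p = 9.95e-05) and Hbb-bs at -0.59 ± 0.05. The 4 globin genes form 2 pairs of near-identical copies, so the division of reads between copies is uncertain.

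**Figure D2:**
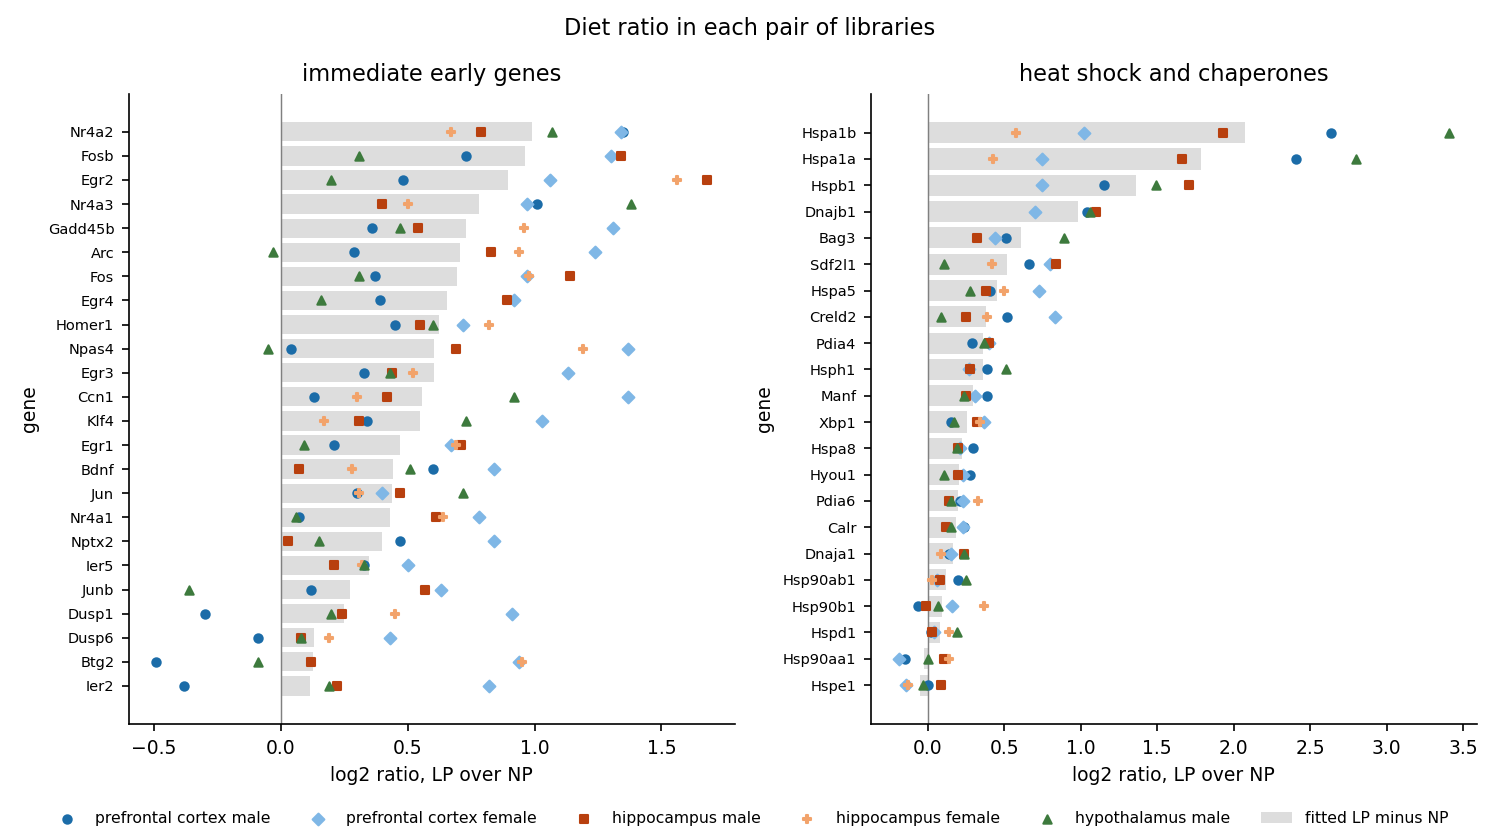
Log2 ratio of LP over NP in each pair (points) and the fitted difference over all pairs (grey bars) for immediate early genes and heat shock genes. All 24 fitted differences of the immediate early list and 20 of the 22 of the heat shock list lie above 0, and genes not counted in the female NP hippocampus have no point for that pair.

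Other lists moved with smaller counts. Among 19 circadian clock genes 3 rose and 16 did not pass (4 higher adjusted over the list alone). They were Per1 (0.40 ± 0.05, adjusted p = 0.00105) and Per2 (0.45 ± 0.05, adjusted p = 0.000642), which are also induced by neuronal activity, and the repressor gene Nfil3 (0.43 ± 0.08, adjusted p = 0.0252). The 25 amino acid response genes regulated by ATF4 had no member past the threshold over all genes by edgeR and 4 higher adjusted over the list alone (18 positive, median 0.11, adjusted p = 0.00139 with an estimated correlation). Myelin and oligodendrocyte genes were all 18 negative in the fit over pairs (median -0.30), although in the male hippocampus pair 12 of 18 were positive (median 0.08). Of these genes 1, Opalin, fell (-0.49 ± 0.10, adjusted p = 0.0334), against 14 lower when adjusted over the list alone. That list's members moved together, and adjusted p = 0.137 with an estimated correlation. Interferon and antigen presentation genes had 2 of 24 higher (5 adjusted over the list alone). They were the class I gene H2-D1 (1.15 ± 0.16, adjusted p = 0.00365) and the class II gene H2-Ab1 (0.98 ± 0.19, adjusted p = 0.0302), and adjusted p = 0.425 with an estimated correlation. Both lie in a stretch of chromosome 17 (34257689 to 35267499) that also holds the heat shock genes Hspa1a and Hspa1b, called higher as well. Of the insulin, leptin and growth list, Irs2, an insulin receptor substrate gene, rose alone among 25 (0.62 ± 0.10), and adjusted p = 0.306 with an estimated correlation. Choroid plexus genes had 1 of 13 higher, the thyroxine carrier gene Ttr (1.36 ± 0.24, adjusted p = 0.0174), and adjusted p = 0.0023 with an estimated correlation. This rests on hippocampus, where the list's medians were 0.54 in males and 0.86 in females, while Ttr was at -0.72 and the list at -0.07 in male prefrontal cortex, and at -0.42 and -0.02 in hypothalamus. Of 15 endothelial genes the glucose transporter gene Slc2a1 rose (0.30 ± 0.05), and adjusted p = 0.509 with an estimated correlation. Of 31 imprinted genes Mest rose (0.38 ± 0.08), with adjusted p = 0.0443 with an estimated correlation. Ttr lost its call with DESeq2 and without the male hippocampus, female hippocampus or female prefrontal cortex pair, and Nfil3, Opalin, H2-Ab1, Slc2a1 and Mest each lost it under 1 or more alternatives. Irs2 and H2-D1 lost it with edgeR's earlier method, and keeping the zeros of the incomplete library left 1 call of 212. Without the hypothalamic pair the interferon and endothelial lists turned direction (adjusted p = 0.723 and 0.985).

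Strong diet differences also lay outside the lists. Nudt13, which encodes a mitochondrial nucleotide hydrolase (ENSMUSG00000021809; chromosome 14, 20294697 to 20317578), fell by 1.91 on the log2 scale (± 0.14 SE, adjusted p = 2.94e-05), with ratios from -1.72 to -1.97 in the 5 pairs. The testis protease gene Capn11 was at -2.50 ± 0.29, with 10 to 82 counts in NP and 1 to 20 in LP. Some others lay in genes with a close copy or in predicted genes. Ndufs5, a complex I subunit gene (ENSMUSG00000028648; chromosome 4, 123712710 to 123718202), fell by 0.80 (± 0.06, adjusted p = 6.39e-05), while its copy BC002163 on chromosome 16, 99.4% identical, rose 1.49-fold (0.57 ± 0.05). The pseudogene Gm11892 on chromosome 4 had 0 to 2 counts in the NP libraries and 17 to 73 in the LP libraries, and the pseudogene Gm10704 on chromosome 3 had 35 to 74 counts in NP and 0 to 8 in LP. Glns-ps1, 96.8% identical to Glul, rose 2.15-fold (1.10 ± 0.10), and 5830417I10Rik, 99% identical to Gon4l over 2893 bases, rose 1.65-fold (0.72 ± 0.07). The counting tool and its handling of shared reads are not given, so values of genes with copies are uncertain.

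Genes of hypothalamic neuropeptides had 5 of 16 members lower (6 adjusted over the list alone), among them Hcrt, the orexin precursor (-2.21 ± 0.17), Oxt (-1.09 ± 0.15) and Avp (-0.92 ± 0.11), but their counts outside the hypothalamus were 0 to 6. These values thus rest on the single hypothalamic pair, as does the dopamine transporter gene Slc6a3 (2.92 ± 0.33). With DESeq2 all 4 lost their calls, and Oxt turned to 0.60. Without that pair the neuropeptide list had adjusted p = 0.985. In total edgeR's quasi-likelihood test called 149 genes higher and 63 lower in LP at an adjusted p of 0.05, and 2412 had an unadjusted p under 0.05. DESeq2 called 132, of which 119 were shared. The count was 72 without the female prefrontal cortex pair (63 shared) and 82 without the male hippocampus pair (73 shared). Of 43 lists, 20 passed camera with the preset correlation, 10 with an estimated correlation, among them immediate early genes (adjusted p = 0.0019), heat shock genes (adjusted p = 1.74e-29) and blood (adjusted p = 1.77e-08), and 4 passed fry, where immediate early genes had adjusted p = 0.168. Those 4 were heat shock, blood, ATF4 targets and hypothalamic transcription factors (0 of 18 past the threshold, 2 higher adjusted over the list alone, adjusted p = 0.0238 with an estimated correlation). Fry and the estimate of the correlation used 8 libraries here, without the female hippocampus pair, so they differ from the preset test in samples as well.

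In prefrontal cortex the diet difference was read from the male and the female pair. Immediate early genes were again the largest group: 12 of 19 members rose and 7 did not pass (16 higher adjusted over the list alone). Nr4a2 was up 2.55-fold (1.35 ± 0.09, adjusted p = 1.72e-06), Nr4a3 1.98-fold (0.99 ± 0.06, adjusted p = 1.72e-06) and the neurotrophin gene Bdnf 1.65-fold (0.72 ± 0.09). Heat shock genes had 5 of 13 higher (9 higher and 1 lower adjusted over the list alone). The inducible Hsp70 genes had the largest values, with Hspa1b up 4.21-fold (2.07 ± 0.31; ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), and Hspa1a, up 3.47-fold (1.79 ± 0.31). These neighbouring genes are near-identical, so their shares of reads are uncertain. Of 10 myelin genes 5 fell and all 10 were lower adjusted over the list alone (median -0.52), with adjusted p = 0.0936 for the list with an estimated correlation. Among them were Mal (-0.52 ± 0.09, adjusted p = 0.0121), Ermn (-0.87 ± 0.17), the central myelin gene Mbp (-0.36 ± 0.07) and Cnp (-0.40 ± 0.08). The male pair carried the larger myelin ratios, at -0.49 for Mbp against -0.22 in the female pair. Hba-a1 and Hba-a2, the 2 blood genes past the threshold, fell by 0.80 ± 0.06 and 0.75 ± 0.06.

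Outside these groups, the histone demethylase gene Kdm6b (0.76 ± 0.08) and the small GTPase gene Gem (1.39 ± 0.17), both induced by activity, rose in prefrontal cortex. Rxfp1, a relaxin receptor gene, fell (-0.90 ± 0.13, adjusted p = 0.00391), as did Map2, which encodes a dendritic microtubule protein (-0.42 ± 0.06, adjusted p = 0.00163), Nudt13 (-1.91 ± 0.25) and Ndufs5 (-0.81 ± 0.10). Ptgs2, the inducible cyclooxygenase gene, was higher (1.24 ± 0.23), with ratios of 0.60 in males and 1.96 in females. It lost its call with edgeR's earlier method and without a low-count filter. The interferon-induced Ifit3 was lower (-2.32 ± 0.49) on 19 and 22 counts in NP against 3 and 5 in LP. The adult neurogenesis, astrocyte and imprinted lists passed camera with the preset correlation and had adjusted p = 0.0936, 0.44 and 0.208 with an estimated correlation. Of 40 lists 6 passed, 2 of them with an estimated correlation (immediate early genes, adjusted p = 0.00838, and heat shock genes, adjusted p = 2.47e-08) and 0 by fry. Over 11433 genes edgeR called 91 higher and 61 lower (1524 at an unadjusted p under 0.05) with 2 residual degrees of freedom. DESeq2 called 25 of these 152 and no others, and left out Mal, Mbp, Cnp, Ermn, Hspa1a, Hspa1b, Gem, Rxfp1, Ifit3 and Nudt13. Without a low-count filter 21 genes passed, and without the male or the female hippocampus pair, which lends its spread, 431 and 497 passed, including all 152. The fits without a hippocampus pair had 1 residual degree of freedom, so their larger counts do not show that the calls are robust.

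In hippocampus, immediate early genes rose as well, with 9 of 19 higher, 10 not past the threshold and 13 higher adjusted over the list alone. All 19 fold changes were positive. The transcription factor gene Egr2 rose 3.16-fold (1.66 ± 0.19, adjusted p = 0.000623; ENSMUSG00000037868, chromosome 10, 67535475 to 67542188), Fos 2.11-fold (1.08 ± 0.13, adjusted p = 0.000958), Nr4a2 1.65-fold (0.72 ± 0.07, adjusted p = 0.000378) and Egr1 1.61-fold (0.69 ± 0.08). Of 13 heat shock genes Hspa5 rose (0.43 ± 0.07, adjusted p = 0.00717), and 9 were higher adjusted over the list alone. Ttr rose 2.90-fold (1.54 ± 0.18, adjusted p = 0.000623), with ratios of 0.99 in males and 2.23 in females, and all 8 choroid plexus genes were positive (median 0.56). Thalamus genes went opposite ways in the same pairs, with all 11 positive in males (median 0.37) and all 7 negative in females (median -0.59). Per1 (0.45 ± 0.07) and H2-D1 (0.91 ± 0.12) rose, and Hba-a1 (-0.43 ± 0.06), Nudt13 (-1.84 ± 0.21) and Ndufs5 (-0.69 ± 0.10) fell. Growth hormone, Gh, was lower in the fit (adjusted p = 0.0429), but the diet pairs went opposite ways: 5319 counts in NP and 5 in LP in males, 2 and 58 in females. The pituitary list with Gh had all 9 members negative in the fit and 1 past the threshold (4 adjusted over the list alone). This direction rests on the male pair, since in the female pair 3 of 8 were positive and 5 negative (Prl 4.80).

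The hippocampal test called 22 genes higher and 9 lower of 11433 by edgeR, with 654 at an unadjusted p under 0.05. DESeq2 called 13 of them, leaving out Egr1, Nudt13, Ndufs5 and Gh among those named, and 5 passed without a low-count filter, Nr4a2 and Nudt13 among them. Of 40 lists 7 passed, 5 of them with an estimated correlation: immediate early genes (adjusted p = 0.000949), heat shock (adjusted p = 3.8e-15), choroid plexus (adjusted p = 2.5e-06), circadian clock (adjusted p = 0.00415) and pituitary (adjusted p = 0.00658). The glucocorticoid and ATF4 lists had adjusted p = 0.473 and 0.241 with an estimated correlation, and 0 lists passed fry.

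Whether the diet difference itself differed between hippocampus and prefrontal cortex was tested over the same 11433 genes. No single gene was found with such a difference: edgeR's quasi-likelihood test called 0 genes, with 592 at an unadjusted p under 0.05. In the simulation this test recovered 28% of changes of 0.5 on the log2 scale. The 0 calls therefore do not show that such differences are absent. DESeq2 called 0, with 43 at an unadjusted p under 0.05, and edgeR's earlier method called 1. At list level the myelin genes, lower with LP in prefrontal cortex, were all 10 positive for hippocampus minus prefrontal cortex (median 0.44), and 8 of 10 passed adjusted over the list alone. The camera test with the preset correlation gave adjusted p = 3.2e-12 for this list, and adjusted p = 0.106 with an estimated correlation. Choroid plexus genes were higher (7 of 8 positive, adjusted p = 0.0492 with an estimated correlation) and striatal neuron genes lower (8 of 10 negative, adjusted p = 0.0492 with an estimated correlation), each with 0 members past the threshold. The pituitary, adult neurogenesis and astrocyte lists also passed with the preset correlation, and had adjusted p = 0.284, 0.126 and 0.578 with an estimated correlation. Without the hypothalamic pair the choroid plexus, striatal neuron, adult neurogenesis and astrocyte lists did not pass, and by fry 0 of the 40 lists passed.

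The diet difference was next compared between the sexes in the 8 prefrontal cortex and hippocampus libraries (10543 genes, female minus male). Of 19 immediate early genes 17 had a positive difference (median 0.36), 2 passed the threshold and 10 were higher adjusted over the list alone, and the list had adjusted p = 0.0699 with an estimated correlation. Btg2, an antiproliferative early gene, had ratios of 0.94 and 0.95 in females and -0.49 and 0.12 in males (prefrontal cortex, then hippocampus; difference 1.18 ± 0.18, adjusted p = 0.00888). Npas4, an activity-dependent transcription factor gene, had 1.37 and 1.19 against 0.04 and 0.69 (1.02 ± 0.17, adjusted p = 0.0166). The Hsp70 genes went the other way, rising more in males: Hspa1b by 2.64 and 1.93 against 1.02 and 0.58 (difference -1.53 ± 0.21, adjusted p = 0.00489) and Hspa1a (-1.46 ± 0.22). Gjb6, an astrocyte connexin gene (0.72 ± 0.11), Plin4, a lipid droplet protein gene induced by glucocorticoids (1.46 ± 0.26), and Ttr (1.22 ± 0.20) were higher in the female response. All 3 lost this call with DESeq2 and when either female pair was left out. Plin4 also lost it without the male prefrontal cortex pair and when genes with 1 residual degree of freedom were added to the test. Btg2, Npas4, Hspa1a and Hspa1b kept their calls with DESeq2. They lost them when either female pair was left out and with edgeR's earlier method.

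The smallest p-values of the sex comparison belonged to genes with copies. The ribosomal protein gene Rps3a1 (ENSMUSG00000028081; chromosome 3, 86137940 to 86142702) had LP over NP ratios of -0.82 and -0.70 in males and -0.07 and 0.00 in females (difference 0.71 ± 0.08, adjusted p = 0.00111). Its intronless copy Rps3a3 on chromosome 13, 98.9% identical, had 1.09 and 1.26 against -0.07 and 0.04 (difference -1.21 ± 0.11, adjusted p = 0.00029). Gm13443, 99.5% identical to Glo1 (1.40 ± 0.14), and the predicted gene 1700020D05Rik (3.73 ± 0.51) had negative LP over NP ratios in males and positive ones in females. Casp9, the initiator caspase gene (ENSMUSG00000028914; chromosome 4, 141793612 to 141815976), had ratios of 1.18 and 0.81 in males and -0.37 and 0.04 in females (difference -1.18 ± 0.14, adjusted p = 0.00129). Crocc, a ciliary rootlet gene, had a difference of -0.77 ± 0.11, not called with DESeq2, and Cyth4, an exchange factor gene, one of 1.27 ± 0.15. Casp9, Rps3a1, 1700020D05Rik and Crocc lost their calls when either female pair was left out. Cyth4 and Gm13443 lost theirs without the female hippocampus pair. The edgeR test called 13 genes higher and 9 lower (707 at an unadjusted p under 0.05) and DESeq2 called 12 of these 22. Without a low-count filter 0 genes passed (703 at an unadjusted p under 0.05). With a pair left out, 5 passed without the female prefrontal cortex pair, 4 without the female hippocampus pair, 53 without the male prefrontal cortex pair and 197 without the male hippocampus pair.

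**Figure D3:**
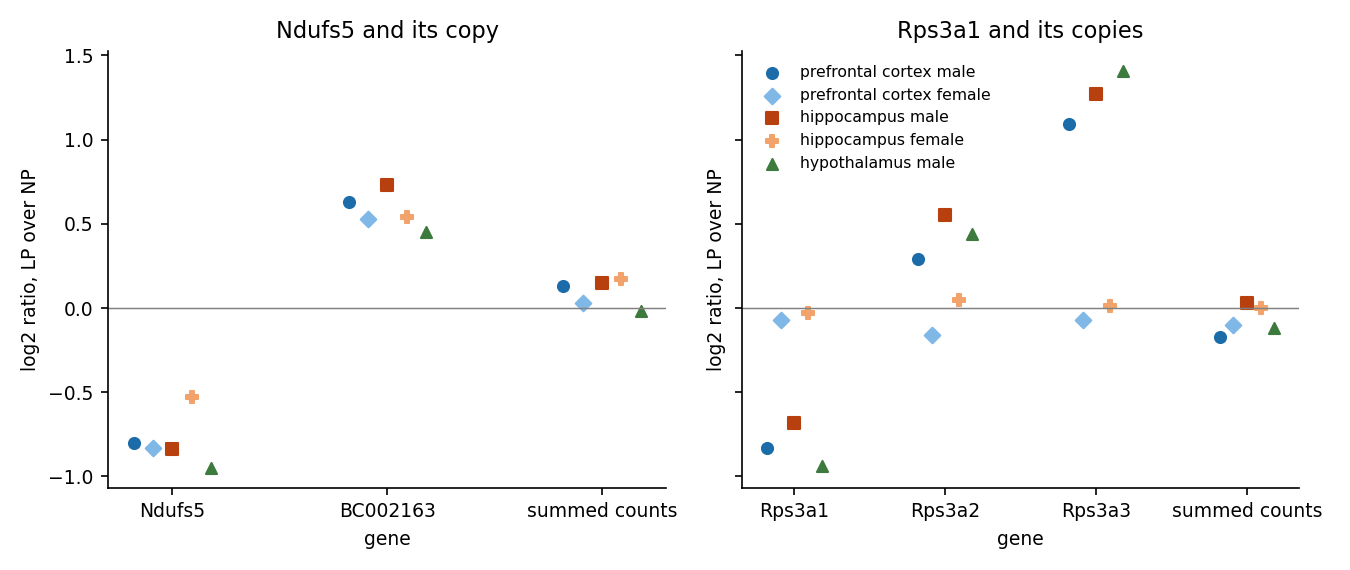
Log2 ratio of LP over NP in each pair for Ndufs5 and its copy BC002163, for Rps3a1 and its copies Rps3a2 and Rps3a3, and for the summed counts of each family. Ndufs5 and BC002163 lie on opposite sides of 0 in all pairs, Rps3a1 and Rps3a3 in the male pairs, and the summed counts lie between -0.17 and 0.17.

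Of 38 lists 8 passed the test between the sexes with the preset correlation and 1, autism risk genes, with an estimated correlation (14 of 21 positive, median 0.07, 2 higher adjusted over the list alone, adjusted p = 0.0376). With an estimated correlation glucocorticoid response genes had adjusted p = 0.0806, ependymal and endothelial genes 0.0764 each, choroid plexus 0.246, thalamus 0.306 and astrocytes 0.362, and 0 lists passed fry. Ttr and the choroid plexus list turned sign without the female hippocampus pair (Ttr -0.82, list adjusted p = 0.75).

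Each region and sex held 1 pair of libraries, so ratios within a pair are values with no replicate check. The title of the hypothalamic LP library ends in a tag whose date-like part differs from that of the other 9 libraries, with no stated meaning, so this pair's diet difference cannot be separated from whatever the tag marks. In the male hypothalamus the inducible Hsp70 gene Hspa1b went from 220 counts (95% Poisson interval 192 to 251) in NP to 2137 (2050 to 2230) in LP, a log2 ratio of 3.41. Slc6a3, the dopamine transporter gene, went from 97 (78.7 to 118) to 779 (725 to 836), Myh11, a smooth muscle myosin gene, from 150 to 539, and H2-D1 from 510 to 1735. Hcrt went from 1523 (1450 to 1600) to 290 (258 to 325), Oxt from 3589 (3470 to 3710) to 1459 (1390 to 1540), and Gh from 1403 to 227. All 17 pericyte, smooth muscle and meningeal fibroblast genes were higher (median 1.16), as were all 24 interferon and antigen presentation genes (median 0.54), 13 of 15 endothelial genes (median 0.62) and all 25 insulin, leptin and growth genes (median 0.33), each at percentile 100, to 1 decimal, among 10000 random lists matched on expression. All 18 myelin genes (median -0.39), 47 of 48 ribosomal protein genes (median -0.18) and 37 of 38 nuclear oxidative phosphorylation genes (median -0.17) were lower, each at percentile 0, to 1 decimal, among the random lists.

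Among genes with mean CPM of at least 10 and separate intervals, to which all rankings here apply, Hspa1b (149 to 1014 counts), Hspa1a (111 to 646) and Gem (76 to 236) had the highest ratios in the male prefrontal cortex pair and the pseudogene Ccl19-ps3 (633 to 315) the lowest. All 18 myelin genes (median -0.76) and 7 of 8 blood genes (median -0.69) were lower in that pair, as were 13 of 17 astrocyte, 13 of 17 pericyte, smooth muscle and meningeal fibroblast, 10 of 15 endothelial and 8 of 12 oligodendrocyte precursor genes (percentiles 0 to 0.7 among the random lists). In the female prefrontal cortex pair all 24 immediate early genes (median 0.93) and all 21 glucocorticoid response genes (median 0.33, against -0.14 in the male pair) were higher, and Ptgs2 (71 to 260 counts), the thrombomodulin gene Thbd (109 to 290) and Klf2 (60 to 154) led, with the helicase-like gene Hltf lowest (141 to 63). In the male hippocampus pair Hspa1b (277 to 1119) and Egr2 (92 to 316) led, and Gh (5319 to 5), the prolactin gene Prl (1223 to 2) and CT010467.1, annotated as ribosomal RNA (800 to 24), were lowest. In the female hippocampus pair Ttr (461 to 2052), Npas4 (150 to 326) and Plin4 (112 to 243) led and Tcf7l2, a thalamic transcription factor gene, was lowest (254 to 126). At least 2-fold differences with separate intervals numbered 12 higher and 1 lower in the male prefrontal cortex, 24 and 1 in the female prefrontal cortex, 12 and 3 in the male hippocampus, 6 and 0 in the female hippocampus over fewer genes, and 73 and 4 in the hypothalamus.

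**Figure D4:**
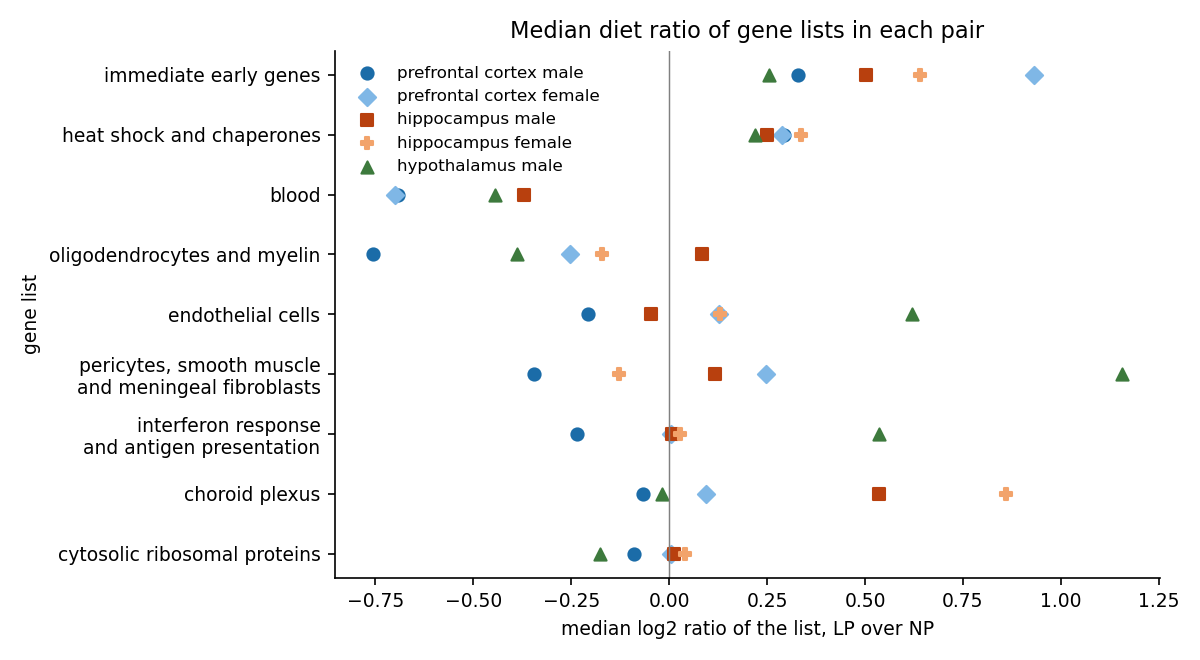
Median log2 ratio of LP over NP of 9 gene lists in each pair of libraries. Immediate early and heat shock genes lie above 0 in all 5 pairs, blood below 0 in the 4 pairs where it had enough members, and pericyte, endothelial and interferon genes are highest in the hypothalamic pair.

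The pairs share no library, so no shared control makes their diet ratios alike. Regions taken from the same animals could do so, and the labels do not say whether they were. The sign-flip permutation takes the pairs as independent. Across 11433 genes, which are not independent replicates, the log2 ratios of 2 pairs correlated on average with r = 0.12 over the 10 combinations, from 0.03 (male against female hippocampus) to 0.21 (male hippocampus against hypothalamus). Of the 16 distinct ways to exchange the diets within pairs, all but the real one gave at most 0.059, and the exact one-sided sign-flip permutation p = 0.0625 is the smallest that 16 flips allow. With Spearman's coefficient the mean was 0.112. For the 7100 genes with mean CPM of at least 10 it was 0.153, with single combinations from -0.19 to 0.32. Pairs of the same sex correlated with a mean of 0.152, and pairs of different sexes with 0.098. These means were 0.115 and 0.111 with Spearman's coefficient, and 0.25 and 0.088 for the 7100 genes.

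To check that the dissected regions carried their known markers, hippocampus was compared with prefrontal cortex (17550 genes, diet and sex in the fit). Hippocampal subfield genes were higher, with 17 of 20 past the threshold upward and 1 downward (adjusted p = 4.94e-09 with an estimated correlation). They included the dentate gyrus transcription factor gene Prox1 (3.36 ± 0.09 SE), the hippocampal transcription factor gene Zbtb20 (3.15 ± 0.09), the mineralocorticoid receptor gene Nr3c2 (2.95 ± 0.05, adjusted p = 6.03e-14) and the lactase gene Lct (5.34 ± 0.13). Dsp, a desmosome gene of the dentate gyrus, had 609 to 812 counts in hippocampal and 0 to 5 in cortical libraries. Neocortical projection neuron genes were lower, with 14 of 18 downward and 4 upward (adjusted p = 0.0322 with an estimated correlation). Examples were Cux2 (-2.72 ± 0.07), Lamp5 (-2.59 ± 0.05, adjusted p = 6.03e-14) and Mef2c (-2.14 ± 0.08). Genes of tissue lining the ventricles were higher in hippocampus, with 12 of 13 choroid plexus genes (Ttr, 461 to 2611 against 7 to 15 counts, and Kl, 3.98 ± 0.16; adjusted p = 1.27e-05 with an estimated correlation) and 10 of 11 ependymal genes (Foxj1, 2.28 ± 0.18; adjusted p = 0.000212 with an estimated correlation).

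All 18 myelin genes were higher in hippocampus (median 1.59), among them Myrf (1.71 ± 0.10), with adjusted p = 0.226 with an estimated correlation. Immediate early genes were lower there in 20 of 24 cases and higher in 3, including Fos (-2.08 ± 0.12) and Egr1 (-1.82 ± 0.10), with adjusted p = 0.184 with an estimated correlation. Of 19 clock genes 14 were lower and 1 higher (adjusted p = 0.00928 with an estimated correlation), and of 17 microglial genes 14 were lower, Csf1r by -0.56 ± 0.06 (adjusted p = 0.226 with an estimated correlation). Of 14 striatal neuron genes 9 were lower and 2 higher (adjusted p = 0.164 with an estimated correlation). In all, 4789 genes were higher and 4577 lower by edgeR (10220 at an unadjusted p under 0.05), and 18 of 43 lists passed, 5 of them with an estimated correlation.

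**Figure D5:**
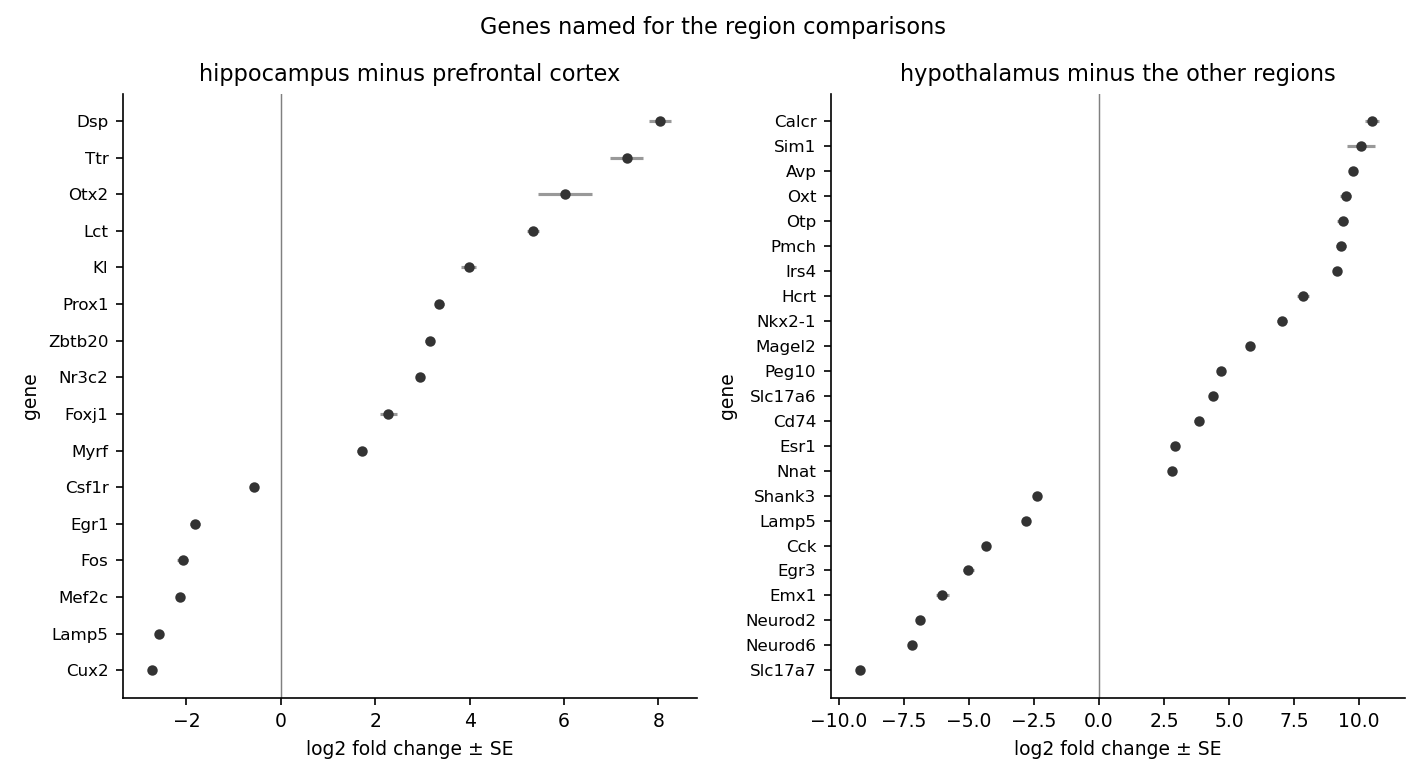
Fitted log2 fold changes with their standard errors for genes named in the region comparisons, hippocampus minus prefrontal cortex (left) and hypothalamus minus the mean of the other regions (right). Hippocampal and hypothalamic markers lie to the right of 0 and cortical markers to the left, and fold changes of genes near 0 counts in one region (Dsp, Otx2, Calcr, Sim1, Otp, Pmch) depend on the prior count.

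The hypothalamus was compared with the mean of the other regions to ask the same of its markers. All 16 neuropeptide genes of the hypothalamic list were higher (adjusted p = 1.32e-08 with an estimated correlation). The 2 hypothalamic libraries held 5402 and 2578 counts of the vasopressin gene Avp, 3589 and 1459 of Oxt, 2193 and 1156 of the melanin-concentrating hormone gene Pmch and 1523 and 290 of Hcrt, against 0 to 6 in the others. Of 18 hypothalamic transcription factor genes 17 were higher and 1 lower (adjusted p = 6.97e-11 with an estimated correlation), with 1089 and 918 counts of Otp, 181 and 165 of Sim1 and 723 and 816 of Nkx2-1 against 0 to 11 elsewhere. The receptor genes Calcr (789 and 669 against 0 to 2) and Esr1 (2.94 ± 0.14) and the receptor substrate gene Irs4 (3061 and 3199 against 2 to 6) followed. Of 31 imprinted genes 28 were higher and 1 lower (adjusted p = 5.25e-08 with an estimated correlation), such as Magel2 (5.79 ± 0.11), Peg10 (4.70 ± 0.09) and Nnat (2.82 ± 0.06). The excitatory neurons differed in transporter, with Slc17a7 at -9.20 ± 0.10 (adjusted p = 1.99e-16) and Slc17a6 at 4.37 ± 0.12. The forebrain transcription factor genes Neurod6 (-7.19 ± 0.16), Neurod2 (-6.88 ± 0.13) and Emx1 (-6.02 ± 0.24) and the peptide gene Cck (-4.34 ± 0.07) were lower.

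Immediate early genes were lower in the hypothalamus, with 23 of 24 past the threshold (Egr3, -5.03 ± 0.21; adjusted p = 0.0675 with an estimated correlation). Autism risk genes had 24 of 38 lower and 5 higher (Shank3, -2.38 ± 0.07; adjusted p = 0.142 with an estimated correlation), interferon and antigen presentation genes 20 of 24 higher (Cd74, 3.83 ± 0.18; adjusted p = 0.189 with an estimated correlation), and neocortical genes 14 of 18 lower and 3 higher (Lamp5, -2.82 ± 0.07; adjusted p = 0.000663 with an estimated correlation). By edgeR 5780 genes were higher and 5335 lower (11693 at an unadjusted p under 0.05), and 18 of 43 lists passed, 9 of them with an estimated correlation. Both hypothalamic libraries were male, and sex was taken out with the additive term.

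Females were compared with males in prefrontal cortex and hippocampus, which also checked the sex labels. Xist, the non-coding RNA of the inactive X chromosome (ENSMUSG00000086503; chromosome X, 103460366 to 103483254), had 2256 to 4242 counts in the 3 female libraries in which it was counted and 2 to 6 in the male ones. The 4 measured Y-linked genes fell, with 210 to 292 counts of Kdm5d in males of these regions and 0 to 1 in the 3 counted female libraries, beside Eif2s3y, Ddx3y and Uty. Of 9 X-linked genes known for female-biased expression 4 rose and 5 did not pass (7 higher adjusted over the list alone). They were Xist, Eif2s3x (0.52 ± 0.05, adjusted p = 2.6e-05), Ddx3x (0.32 ± 0.05) and Kdm5c (0.27 ± 0.06). Immediate early genes were lower in females, with 12 of 24 down, 1 up and 11 not past the threshold (18 lower and 4 higher adjusted over the list alone). Fos fell by 1.15 on the log2 scale (± 0.08, adjusted p = 1.98e-05), Ccn1, a secreted matrix protein gene, by 1.64 (± 0.17, adjusted p = 0.000477), Nr4a1 by 0.75 (± 0.08) and Junb by 0.63 (± 0.08). Dnajb1 was lower too (-0.58 ± 0.07). Hif3a, which glucocorticoids induce, was higher (1.15 ± 0.14, adjusted p = 0.000349). Of 19 clock genes, Per2 rose (0.41 ± 0.06), Arntl fell (-0.35 ± 0.07), and 8 were higher and 1 lower adjusted over the list alone. Arntl, Junb and Kdm5c lost their calls with DESeq2, and Per2 without any 1 library of prefrontal cortex. Ccn1 and Nr4a1 lost theirs with edgeR's earlier method, and Ddx3x without a low-count filter and with 10 libraries and additive terms.

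The sex comparison called 33 genes higher and 36 lower of 16273 by edgeR (1445 at an unadjusted p under 0.05), and DESeq2 called 36, 34 of them shared. With 1 library left out only genes counted in all libraries could be fitted in most cases: 8 genes passed without the male or the female NP library of prefrontal cortex, 23 without either LP library of prefrontal cortex and 24 without either LP library of hippocampus. Of 41 lists 10 passed, and 5 with an estimated correlation: immediate early genes (adjusted p = 0.0175), X-linked genes (adjusted p = 5.74e-18), circadian clock (adjusted p = 1.47e-05), thalamus (adjusted p = 0.000547) and neurotrophins (adjusted p = 0.0324). Myelin genes had 5 of 18 lower adjusted over the list alone and 0 by edgeR over all genes (adjusted p = 0.571 with an estimated correlation), and their direction turned without the NP pair of prefrontal cortex.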

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

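All tests of explanations below were chosen after the results were seen. A test of the difference itself flagged 3 results: the diet difference differed between the sexes in 22 genes and in 8 gene lists, and between prefrontal cortex and hippocampus in 6 gene lists. With DESeq2 12 of the genes remained and without a filter on low counts 0. With an estimated correlation 1 of the 8 and 2 of the 6 lists remained, by fry 0. The test between sexes takes prefrontal cortex and hippocampus as replicates within a sex. If both regions came from the same animals, a difference between the animals of the diet groups would read as a difference between the sexes. The male hypothalamic pair, not in this test, had ratios of -0.94 for Rps3a1, 1.41 for Rps3a3 and -0.38 for Gm13443. The other male pairs had -0.83 and -0.68, 1.09 and 1.27, and -0.48 and -0.32. The female pairs had -0.07 and -0.03, -0.07 and 0.01, and 0.94 and 1.05. A response of males to diet would look the same, so these values do not decide.

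Some genes called for diet lay close together or were copies of other genes: 81 of 212 had another called gene within 1 megabase, against a median of 56 in 10000 random draws (permutation p = 0.0017), and for diet by sex 6 of 22 against 0 (permutation p = 0.0105). Outside the fixed lists this was 45 of 157 against 32 (permutation p = 0.0386), but without a family of predicted genes on chromosome 14 this was 35 of 147 against 29 (permutation p = 0.181), and for diet by sex 2 of 15 (permutation p = 0.226). The counts outside the lists leave out H2-Ab1, Hspa1b, Hspa1a and H2-D1. These 4 called genes lay together on chromosome 17 (34257689 to 35267499), all higher in LP. Alleles that differ between the animals of the diet groups can therefore not be told, and an effect of diet on the called genes that lie close together stays open as well. Reads shared between gene copies fit for Ndufs5 and BC002163, whose summed counts differed by a mean log2 of 0.09 (alone -0.79 and 0.58). The summed counts of Rps3a1, Rps3a2 and Rps3a3 differed by -0.07 (alone -0.51, 0.23 and 0.74). Sharing that is the same in both diets would not by itself give opposite ratios, so what differed between the diet groups is not told. By contrast, summed counts of Gon4l and 5830417I10Rik differed by 0.34, and those of Glo1 and Gm13443 by -0.29 in males and 0.41 in females. Pseudogenes made up 9.43% of called and 7.03% of tested genes (Fisher's exact p = 0.175), which does not decide whether shared reads are common among the calls.

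Immediate early and heat shock genes were higher in the LP libraries. A different time of day at collection would move the clock. Over all pairs the 17 clock genes other than Per1 and Per2 had a median absolute log2 difference of 0.07, against 0.55 for immediate early genes. Of the 17, 1 was called, Nfil3 (0.43). This argues against a large shift of the clock shared by the pairs. A small shift, or one in single pairs, is not excluded. In the male hippocampus pair 15 of 19 clock genes, Per1 and Per2 included, were higher and 4 lower (median 0.13). Handling or arousal before collection cannot be told apart from diet. Within the NP libraries alone the female minus male medians of immediate early genes were -0.77 and -0.47, a mean absolute difference of 0.62. In the LP libraries these medians were -0.31 and -0.54 (prefrontal cortex, then hippocampus), so handling cannot be told apart from a sex difference here either. Between the sexes the clock list passed its test with an estimated correlation, with Per2 higher and Arntl lower in females, calls that some alternatives lost. A time of collection that differs between the sexes was not tested and stays open. In the prefrontal cortex all 21 glucocorticoid response genes were higher with LP in females (median 0.33) but 8 of 21 in males (median -0.14). The labels used here state no time of collection, and the meaning of a date-like part of the titles, which differs only in the hypothalamic LP library, is not given, so an effect of perinatal diet on activity-dependent transcription stays open.

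Pituitary hormone transcripts appeared in the male NP hippocampus library, with 5319 counts of Gh and 1223 of Prl. Carry-over from the male NP hypothalamus library is excluded, since it implies 34090 counts of Oxt and Avp together and 4 were found. Pituitary cells that make Gh and Prl stay open. Of 5 other pituitary genes 1, Cga (20 counts against 0 to 1), had a Poisson interval above those of the other hippocampus libraries. Fshb had 8 counts and Pou1f1 7, against 0 in the others, with intervals that were not separate. Lhb at 8 and Tshb at 12 did not exceed the highest of the others, 9 and 12. A piece of pituitary with all of its hormone cells is excluded by 22 counts of Pomc, within the 15 to 25 of the others. Local expression of Gh and Prl under the NP diet was not tested apart from this.

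Other splits of the libraries were counted as well. The diet split gave the most called genes of 100 splits of 5 against 5 (212, highest other 112; 1 of 100 reached it) and of the 16 exchanges within strata (highest other 32; 1 of 16, too few splits for a rate under 0.05). The sex split gave the most of 32 splits that could be fitted (69, highest other 32, 1 of 32). The split of prefrontal cortex against hippocampus gave the most of 35 (9366, highest other 5, 1 of 35). Strata stayed in the diet and sex fits, so a split with both libraries of a stratum in 1 group drew on fewer pairs. This favoured the real diet and sex splits in advance. Other splits of the regions left the region difference in the spread, so few calls could arise. The shares 1 of 100, 1 of 32 and 1 of 35 are therefore not rates of chance.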

How the results depend on the processing

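Counts of called genes depended on the test, the filter and the libraries, and counts for the regions moved least in relative size. Depth and 1 library per group limit every diet result, and the incomplete library limits genes on its far side. The diet and sex tests compare libraries within strata. By replicate number, no paired analysis was possible because each group holds 1 library and groups share only the number 1. The settings with zeros kept, with genes added at 1 residual degree of freedom and with summed counts were chosen after seeing the data. Not run, since the fit needs them, were the diet tests within a region without a pair of that region and the test between regions without a pair of either. The hypothalamus libraries are not part of the tests between sexes, so leaving them out was not run there. Unless construction shows it, the cause was not tested.

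With DESeq2's Wald test 132 genes were called for diet over all regions (main 212), 25 in prefrontal cortex (main 152), 13 in hippocampus (main 31), 12 for diet by sex (main 22) and 36 between the sexes (main 69), and Oxt turned to 0.60. Region counts were 7664 for prefrontal cortex against hippocampus and 9032 for hypothalamus. With no filter on low counts prefrontal cortex had 21, hippocampus 5, diet by sex 0 and sex 30. The earlier quasi-likelihood method called 247 in prefrontal cortex and 1 for diet by region, where the other settings gave 0. With only the 4 libraries of the region 499 were called in prefrontal cortex and 68 in hippocampus, each with 1 residual degree of freedom. With 10 libraries and additive terms 28 were called between the sexes. DESeq2's size factors in edgeR gave 213, 153, 31, 0, 21 and 64 for diet over all regions, prefrontal cortex, hippocampus, diet by region, diet by sex and sex.

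With the zeros of the incomplete library kept, 1 gene was called for diet over all regions, 0 in prefrontal cortex, 0 in hippocampus, 0 for diet by sex, 0 between the sexes, 5300 for prefrontal cortex against hippocampus (main 9366, 836 of which turned sign) and 5990 for hypothalamus (main 11115), and Oxt turned to 0.63. By construction the zeros enter scaling and spread. With genes added at 1 residual degree of freedom 430 were called in prefrontal cortex. With counts summed over regions 325 were called for diet and 161 between the sexes, over fewer genes, and lists that turned direction were pericytes, smooth muscle and meningeal fibroblasts for diet (adjusted p = 0.648) and myelin for sex (adjusted p = 0.254).

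Leaving out 1 pair or library gave 72 to 246 genes for diet over all regions, 172 to 497 in prefrontal cortex, 29 to 37 in hippocampus, 0 for diet by region, 4 to 197 for diet by sex, 8062 to 9909 for prefrontal cortex against hippocampus, 9677 to 11073 for hypothalamus and 8 to 91 between the sexes. Without the hypothalamus pair, which leaves the 8 prefrontal cortex and hippocampus libraries, lists that turned direction for diet were neuropeptides, endothelial cells and pericytes (adjusted p = 0.985 each), interferon (adjusted p = 0.723) and oxidative phosphorylation (adjusted p = 0.951), with lowest values of 2.58e-05, 1.03e-05, 3.9e-15, 5.51e-07 and 0.000305 without another pair. Without the female hippocampus pair Ttr for diet by sex turned to -0.82 (highest 3.02 without another pair) and the choroid plexus list turned with adjusted p = 0.75 (lowest 0.00312). Without either NP library of prefrontal cortex the myelin list for sex turned (adjusted p = 0.3; range 3.24e-12 to 0.318).

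The preset list test called 20 lists for diet over all regions, 6 in prefrontal cortex, 7 in hippocampus, 6 for diet by region, 8 for diet by sex, 18 for prefrontal cortex against hippocampus, 18 for hypothalamus and 10 for sex. In that order, of all lists tested, camera with an estimated correlation called 10, 2, 5, 2, 1, 5, 9 and 5 and fry 4, 0, 0, 0, 0, 30, 35 and 1. For diet over all regions, the region comparisons and sex, fry and the estimate of the correlation used fewer libraries than the preset test. Agreement between pairs was 0.153 for genes with mean CPM of at least 10 (-0.19 to 0.32) and 0.112 with Spearman's coefficient (main 0.12). Prior counts of 0.5 and 5 gave 6 to 79 and 6 to 81 differences of 2-fold in single pairs (main 6 to 77).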

Other observations

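Several lists not described above differed between regions. In hippocampus against prefrontal cortex 34 of 48 cytosolic ribosomal protein genes and 27 of 38 nuclear oxidative phosphorylation genes were lower (1 of the latter higher), with adjusted p = 0.466 and 0.482 with an estimated correlation. In hypothalamus against the other regions all 17 microglial genes were lower (median -0.71, adjusted p = 0.2 with an estimated correlation), all 11 ependymal genes higher (median 3.29, adjusted p = 1.15e-06 with an estimated correlation), and 14 of 20 oxytocin, vasopressin and social behaviour genes higher with 3 lower (adjusted p = 0.000663 with an estimated correlation). Of 26 synaptic vesicle release genes 20 were lower and 2 higher (adjusted p = 0.0398 with an estimated correlation).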
